A study of Mus musculus with 45 samples.

How the data were processed

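Liver and kidney RNA of male mice, CBA/Ca per the labels and BALB/c per the series text, was hybridised to NimbleGen single-colour arrays with 137604 probes, 2 arrays per sample, for 45 samples and 90 arrays on 10 slides. Groups, diet and time were taken from the sample labels. An array carried 135054 gene probes and 2550 random-sequence control probes. The gene probes formed 42575 probe sets, 35234 with 3 probes, 7336 with 4 and 5 with fewer.

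The files per array hold probe intensity on a linear scale, per the file headers. From the values, the authors had already quantile normalized the intensity within each slide, and the mismatch column was 0 throughout. The deposited table per sample is on the log2 scale. The submitters' processing notes name RMA without a version. In 43 of 45 columns the deposited log2 value equalled the mean log2 intensity over the probes and both arrays of the sample, within a tolerance of 1e-06. The 2 columns that deviated were liver B control 3, which matched its first array alone, and kidney B diet 6, which matched the mean of its first array and the second array of kidney B diet 2. The array files were therefore used, and the deposited table served as an alternative.

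Intensities were background corrected with normexp, which moved the median of an array by between -11.0 and -5.70 intensity units before an offset of 50 was added. They were quantile normalized over all arrays of a tissue, and summarised per probe set by median polish with 10 iterations on the log2 scale. For comparisons between tissues all 90 arrays were normalized together. The 2 arrays of a sample were averaged. The background level was the 95th percentile of the random-sequence probes after the same steps, 7.93 in liver and 7.92 in kidney. No probe set was removed for low signal. Where 1 group of a named gene lay under the background, a fold change is a lower bound at best.

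Each tissue was fitted with 4 groups, and both tissues together with 8, in limma 3.58.1 (lmFit and eBayes) on R 4.3.3 with matrixStats 1.5.0. The contrasts were diet minus control in groups A and B, the effect in A minus that in B, and the effect in liver minus that in kidney. All tests were two-sided. The p values were adjusted by Benjamini-Hochberg over all 42575 probe sets with a threshold of 0.05. Plots were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.

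Gene names came from the identifiers in the array description matched to a table of mouse genes by Entrez ID (38545 probe sets) or accession (98), and 3932 stayed without a name. A gene was represented by the probe set with the highest mean over the tissue's samples. The genes named in the text follow a rule. Per diet comparison these are the 12 largest rises and the 12 largest falls among called genes with a mean above background in at least 1 group, without clone, model or accession names. If fewer than 5 passed, the 5 smallest p values were added. For each difference of effects 6 genes were named each way. Further genes of methyl group metabolism were always followed (among them Bhmt, Mat1a, Gnmt, Cbs, Chdh, Pemt, Mtr, Ahcy and Dnmt1), and up to 4 called members per gene list as examples. Alb and the sample scores were named after their values had been seen.

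Gene lists, 28 by function and 21 of cell type or tissue markers, were written from general knowledge, and 40 were tested per tissue. Each was tested with camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 40 lists, and with an estimated correlation as the alternative. Members past the threshold were counted over all probe sets and again adjusted over the list alone. A sample's score on a marker list was the mean over its members of the log2 deviation from that gene's median over the samples of the tissue. Where samples are counted for a list of genes, a diet sample's median deviation from the control means over the members was set against that of the median control. The levels of the 2 sets of controls were compared in the same limma fit after the results had been seen.

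The comparisons, the gene lists, the rule for named genes and the alternatives were set before the data were examined, apart from those named as added. The alternatives were no background correction, normexp with offset 0, cyclic loess, median scaling, all samples normalized together, the mean of probes, the deposited table, a filter on dim probe sets, a 1.5-fold minimum, eBayes with trend and robust, each array of a sample alone, the slide as a block in a fit on single arrays with the sample as a random block, the replicate number (for the tissues, the group and male number) as a block, the compared groups normalized and fitted alone, and each animal left out in turn without new normalization. Added alternatives were fits within single slides, the fit on single arrays without the slide block, the compared groups fitted alone without new normalization, fits without samples whose arrays correlated poorly, fits without kidneys that carried adrenal or pancreas transcripts, and a fit with 4 tissue scores as covariates.

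Whether equal replicate numbers pair samples was checked by correlating their deviations from the group means. In kidney group B all 6 pairs correlated (r from 0.24 to 0.45 across probe sets) and each number's best match was its own, so the blocked count is given there. Equal numbers also lay side by side on both slides in that group. In liver A (-0.09 to 0.25), liver B (-0.32 to 0.11) and kidney A (-0.28 to 0.38) numbers did not pair samples. The labels give the same group and male numbers in both tissues without stating that the animals are the same. The correlation within such numbers was 0.02.

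The fit was tested on simulated data of the same size for each diet comparison. In liver A it recovered 68.0% of 100 probe sets changed 1.5-fold, in liver B 63.0%, in kidney A 68.0% and in kidney B 71.0%. At 2-fold it recovered 94.0%, 95.0%, 98.0% and 94.0% in the same order. The runs with both sizes of change held 6, 8, 7 and 10 false calls. The simulated noise was independent between probe sets and between samples, without the slides and numbered pairs of the real arrays. These runs therefore give no rate of false calls for the real data. The number of arrays limits the precision.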

Results

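RNA was measured in the liver and kidney of male mice on single-colour expression arrays. The sample labels give the inbred strain CBA/Ca, while the text of the series names BALB/c. Methionine, choline and folic acid supply the methyl groups that cells use to methylate DNA, lipids and small molecules. Animals of group A were fed for 8 weeks on a diet low in methionine and without choline and folic acid. Animals of group B had the same 8 weeks and then 2 weeks of normal diet. Each group had its own controls. The liver set held 6 control and 6 diet animals in group A and 5 and 5 in group B. The kidney set held 6 control and 5 diet animals in group A and 6 and 6 in group B. All 45 samples were hybridised to 2 arrays each, which makes 90 arrays on 10 slides. Each array measured 42575 probe sets, of which 38643 carried the name of 1 gene, for 21698 genes in all. In liver 55.6% and in kidney 59.3% of the probe sets had a mean above the level of random-sequence control probes, which was 7.93 and 7.92 on the log2 scale. An array has no read depth, and the number of arrays limits the precision. Differences below are on the log2 scale with the standard error of the limma fit, as diet minus control, and a gene "rose" or "fell" only where its adjusted p was under 0.05.

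The first comparison asked what 8 weeks on the deficient diet did to the liver. Genes of macrophages and inflammation, of the extracellular matrix and of cell division rose together, while genes of fatty acid and cholesterol synthesis fell. Mmp12, an elastase of macrophages, rose by 4.18 ± 0.19 (SE, n = 6 and 6) from a control mean of 7.57, under the background, and Lcn2, an iron-binding protein of the acute phase, by 4.04 ± 0.18, or 16.4-fold. Cidec, a protein of lipid droplets, rose by 3.75 ± 0.23, and Gsta1, a glutathione transferase, by 3.68 ± 0.14. Pnpla3, a lipase-family gene driven by feeding, fell by 3.60 ± 0.20, or 12.1-fold. Its neighbour in sequence Pnpla5 fell by 3.71 ± 0.20 to a diet mean of 7.58, under the background. Slc2a4, the insulin-responsive glucose transporter, fell by 2.90 ± 0.15. The other genes among the 12 largest rises were D17H6S56E-5, Cib3, Ly6d, Ccn5, Ubd, Gpnmb, Abcc12 and Slpi, between 3.45 and 4.36. The other genes among the 12 largest falls were Sorcs2, Obp2a, Ces4a, Lrit2, Pitx3, Adgrv1, Rnase2a, Slc34a2 and Moxd1, between -3.51 and -2.19. The controls of Ccn5, Ubd, Gpnmb and Abcc12 and the diet livers of Sorcs2, Obp2a, Pitx3, Rnase2a and Moxd1 also averaged under the background.

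All 42 measured members of the macrophage and chemokine list rose, with a median of 1.23 (42 adjusted over the list alone). Among them were Itgax, a leukocyte integrin (3.15), Cd14, a receptor for bacterial endotoxin (3.01), Ccl2, a chemokine that attracts monocytes (2.84), and the galectin Lgals3 (2.04). Of the 36 genes of the extracellular matrix and fibrosis list, 30 rose and 1 fell (31 and 1 adjusted over the list alone), with a median of 1.08, among them the collagenase Mmp13 (3.08), Timp1, an inhibitor of matrix proteases (2.98), and the collagen chain Col1a2 (1.63). Of the 33 interferon response genes 22 rose (25 adjusted over the list alone), with Oas1a at 1.62 and Zbp1 at 1.61. Of the 27 acute phase genes 10 rose and 1 fell (10 and 1 adjusted over the list alone), with Il1rn, which blocks the interleukin-1 receptor, at 2.68, Orm2 at 2.09 and Saa3 at 1.40. The adjusted p of the camera test was 3.2e-40 for the macrophage list, 1.5e-23 for the matrix list, 1.2e-11 for the interferon list and 7.7e-05 for the acute phase list. By the median of the members, all 6 diet livers lay above the median control liver on the macrophage, matrix and interferon lists.

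Of the 35 cell cycle genes 31 rose, with a mean of 1.52 (32 rose and 1 fell adjusted over the list alone, camera adjusted p = 1.1e-30). The cyclins Ccnb1 (3.39) and Ccnb2 (2.83), which drive entry into mitosis, and Mki67 (2.86), a marker of dividing cells, were among them. Targets of p53 rose in 13 and fell in 2 of 25 cases (13 and 3 adjusted over the list alone, camera adjusted p = 2.3e-05), with Gtse1 at 2.05, the death receptor Tnfrsf10b at 2.01 and Phlda3 at 1.67. Of the 18 fetal liver and liver tumour genes 9 rose and 3 fell (11 and 3 adjusted over the list alone, camera adjusted p = 7.7e-05), led by the imprinted noncoding RNA H19 (3.16), Golm1 (1.95), Spink1 (1.92) and Sox4 (1.49).

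Stress responses rose as well. Of the 39 genes of the ATF4 and amino acid response 23 rose and 1 fell (25 and 2 adjusted over the list alone, camera adjusted p = 3.1e-08), among them the transcription factor Atf3 (3.24), the stress hormone Gdf15 (2.33) and Slc7a1, a transporter of cationic amino acids (1.74). Of the 41 NRF2 and glutathione genes 18 rose and 1 fell (19 and 3 adjusted over the list alone, camera adjusted p = 3.3e-07), with Gsta2 at 3.44, Gpx7 at 2.30 and Srxn1 at 1.24 beside Gsta1. Chaperones of the endoplasmic reticulum did not move as a group, with 2 of 24 higher and 4 lower (2 and 2 adjusted over the list alone, camera adjusted p = 0.959).

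Genes of lipid synthesis fell. In the fatty acid and triglyceride synthesis list 17 of 25 fell (19 adjusted over the list alone, camera adjusted p = 3.1e-08), including Thrsp, a regulator of lipogenesis (-2.09), the elongase Elovl6 (-1.33) and Acly, which makes acetyl-CoA for lipid synthesis (-1.08). In the cholesterol synthesis list 18 of 25 fell (19 adjusted over the list alone, camera adjusted p = 1.8e-09), including Tm7sf2 (-1.11), Hsd17b7 (-0.94) and Sqle (-0.74). Targets of PPAR alpha and fatty acid oxidation had 9 of 40 genes higher and none lower (9 adjusted over the list alone), led by Cyp4a14 (3.12) and Acot2 (1.40), but the list did not pass as a whole (camera adjusted p = 0.108). Of the 30 lipid droplet and lipoprotein genes 8 rose and 6 fell (9 and 6 adjusted over the list alone, camera adjusted p = 0.468), and Plin4, a lipid droplet coat protein, rose by 1.52. Of the 23 gluconeogenesis and glucocorticoid targets 1 rose and 7 fell (1 and 8 adjusted over the list alone), among them Lpin1 (-1.22) and Tsc22d3 (-1.16). The adjusted p of that list was 0.038, and adjusted p = 0.095 with an estimated correlation.

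Male-biased liver genes fell in 17 of 25 cases (1 rose and 17 fell adjusted over the list alone, camera adjusted p = 5.6e-06), among them Cyp2u1 (-1.31), Susd4 (-1.25) and Slco1a1, a bile acid and steroid transporter (-0.94). Of the 31 female-biased genes 9 rose and 4 fell (9 and 5 adjusted over the list alone, camera adjusted p = 0.422). Bile acid synthesis and transport had 5 of 25 genes higher and 9 lower (5 and 10 adjusted over the list alone, camera adjusted p = 0.395), with the exporter subunit Slc51b at 1.66 and the uptake carrier Slc10a1 at -0.64. Cytochromes P450 and conjugating enzymes for foreign compounds had 7 of 38 higher and 12 lower (7 and 18 adjusted over the list alone, camera adjusted p = 0.080), with Cyp2c29 at -1.74. The 21 clock genes had 3 higher and 6 lower (3 and 6 adjusted over the list alone, camera adjusted p = 0.161), with Per2 at -1.35 and Npas2 at -1.12.

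Genes of the pathways that make and use methyl groups moved in both directions. In the methionine cycle and folate list 5 of 40 genes rose and 11 fell (5 and 12 adjusted over the list alone, camera adjusted p = 0.098). Mthfd1l, a mitochondrial folate enzyme, rose by 1.84 and Mat2a, which makes S-adenosylmethionine outside adult hepatocytes, by 0.90. Gnmt, the glycine methyltransferase that disposes of surplus S-adenosylmethionine, fell by 0.44 ± 0.08. Neither Bhmt (-0.06 ± 0.07), Mat1a (-0.07 ± 0.10), Cbs (-0.14 ± 0.08), Mtr (0.04 ± 0.09) nor Ahcy (-0.19 ± 0.08) passed the threshold. In the choline and phosphatidylcholine list 3 of 29 rose and 6 fell (3 and 6 adjusted over the list alone, camera adjusted p = 0.731), with the choline transporter Slc44a1 at -0.73, while Chdh, which oxidises choline, rose by 0.27 ± 0.08 and Pemt (0.05 ± 0.08) did not pass. Small-molecule methyltransferases and polyamine genes had 4 of 21 higher and 5 lower (4 and 5 adjusted over the list alone, camera adjusted p = 0.997), with Inmt at -1.34 and Smox at 1.00. Of 25 genes of the DNA methylation machinery 9 rose and 2 fell (9 and 3 adjusted over the list alone), among them Gadd45b (2.45), Mbd4 (0.71) and the maintenance methyltransferase Dnmt1 (0.51 ± 0.08). That list had a camera adjusted p = 0.039, and adjusted p = 0.092 with an estimated correlation. Of 28 imprinted genes 3 rose and 4 fell (3 and 4 adjusted over the list alone, camera adjusted p = 0.610). Of 24 germline genes that promoter methylation keeps silent, only 2 of which had a mean above background, none rose and 4 fell (2 adjusted over the list alone, camera adjusted p = 0.259).

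Markers of cell types moved unequally beside these groups. Cholangiocyte markers rose in 5 of 9 cases (6 adjusted over the list alone), with a median of 0.59 and Spp1 at 1.47, Cldn4 at 1.31 and Epcam at 1.22. The camera adjusted p was 3.7e-04, and adjusted p = 0.096 with an estimated correlation. Stellate cell markers rose in 6 of 10 cases (7 adjusted over the list alone) with a median of 0.37, camera adjusted p = 0.003, and adjusted p = 0.096 with an estimated correlation. Kupffer cell markers rose in 3 of 8 cases (3 adjusted over the list alone, median 0.19, camera adjusted p = 0.080), and sinusoidal endothelium had 1 of 9 higher and 1 lower (1 and 1 adjusted over the list alone), with a median of -0.05, a mean of 0.03 and a camera adjusted p = 0.959. Hepatocyte markers had a median of -0.03, and 1 of 14, the urea cycle enzyme Arg1 (-0.47), fell (1 adjusted over the list alone, camera adjusted p = 0.585). Red blood cell markers fell in 5 of 9 cases (5 adjusted over the list alone, median -0.41, camera adjusted p = 0.040, and adjusted p = 0.141 with an estimated correlation). The lists of T cells, B and plasma cells, neutrophils, adipocytes, adrenal cortex, skeletal muscle, exocrine pancreas and gallbladder or bowel did not pass, with camera adjusted p = 0.730, 0.857, 0.530, 0.635, 0.656, 0.516, 0.379 and 0.635. Median, mean and test differed in sign for the T cell, adipocyte, adrenal and endothelial lists.

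In all, 12195 of the 42575 probe sets differed in group A livers, 6093 higher and 6102 lower. Of these 4090 differed by at least 1.5-fold, 2816 higher and 1274 lower. In each of the 24 genes with the largest rises and falls, which were chosen for their size in these samples, all 6 diet livers lay on the same side of the control mean. Of the 40 lists tested 17 passed, 12 up and 5 down, and 12 passed with an estimated correlation. Only 1 slide held several animals of both groups, and its 6 controls and 5 diet animals gave 6510 probe sets, with 97.7% of the full set's calls in the same direction there. A fit on single arrays with the sample as a random block gave 12643 probe sets and kept 11651 of the 12195 calls. With the slide as a further block it gave 9487 and kept 7938, while 180 had the opposite sign. The median SE of the 12195 was 1.22 times as large, and their differences followed those without the block at a slope of 0.96, which large differences dominate.

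**Figure D1:**
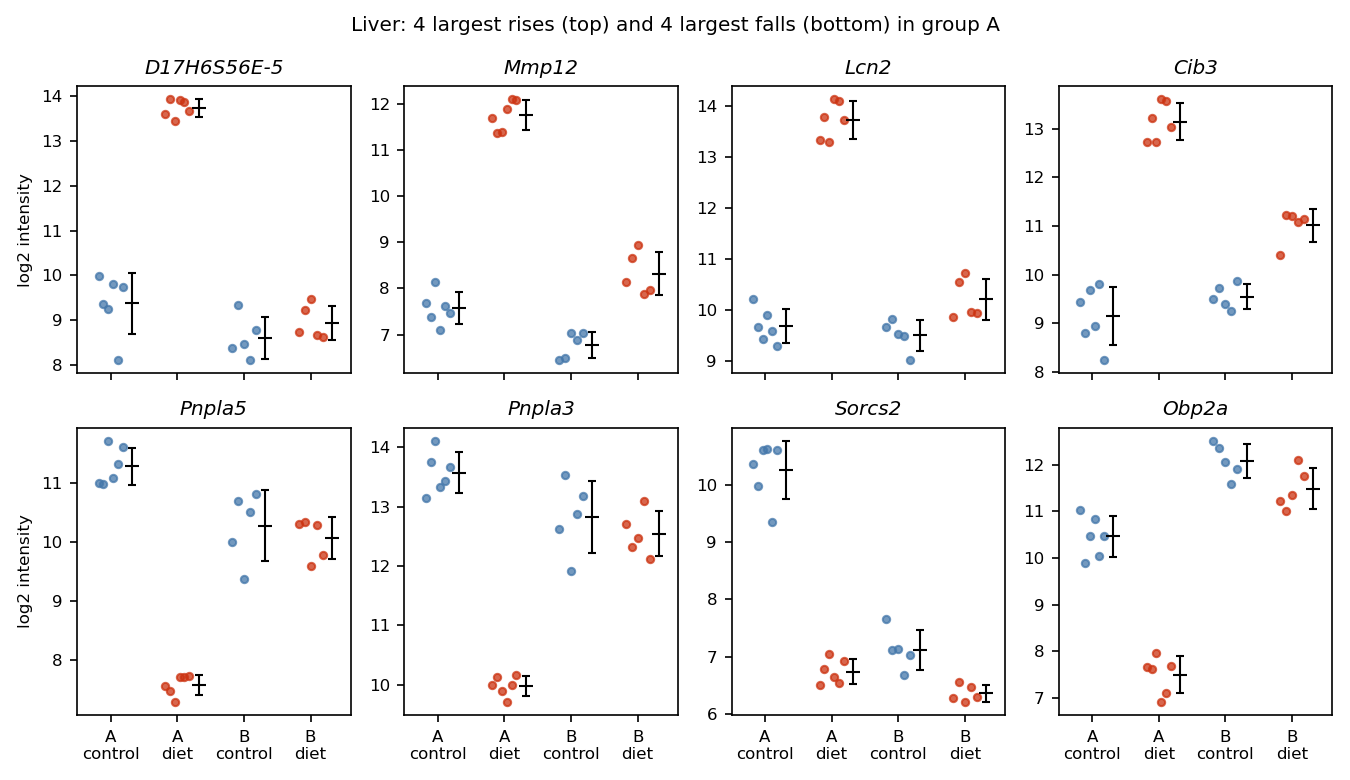
Log2 intensity per liver sample for the 4 largest rises (top) and the 4 largest falls (bottom) of group A, with controls in blue, diet animals in red, and the mean with its SD beside each group. In Mmp12 the group A diet livers averaged 11.75 against 7.57 in their controls, and the group B diet livers 8.32 against 6.78.

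**Figure D2:**
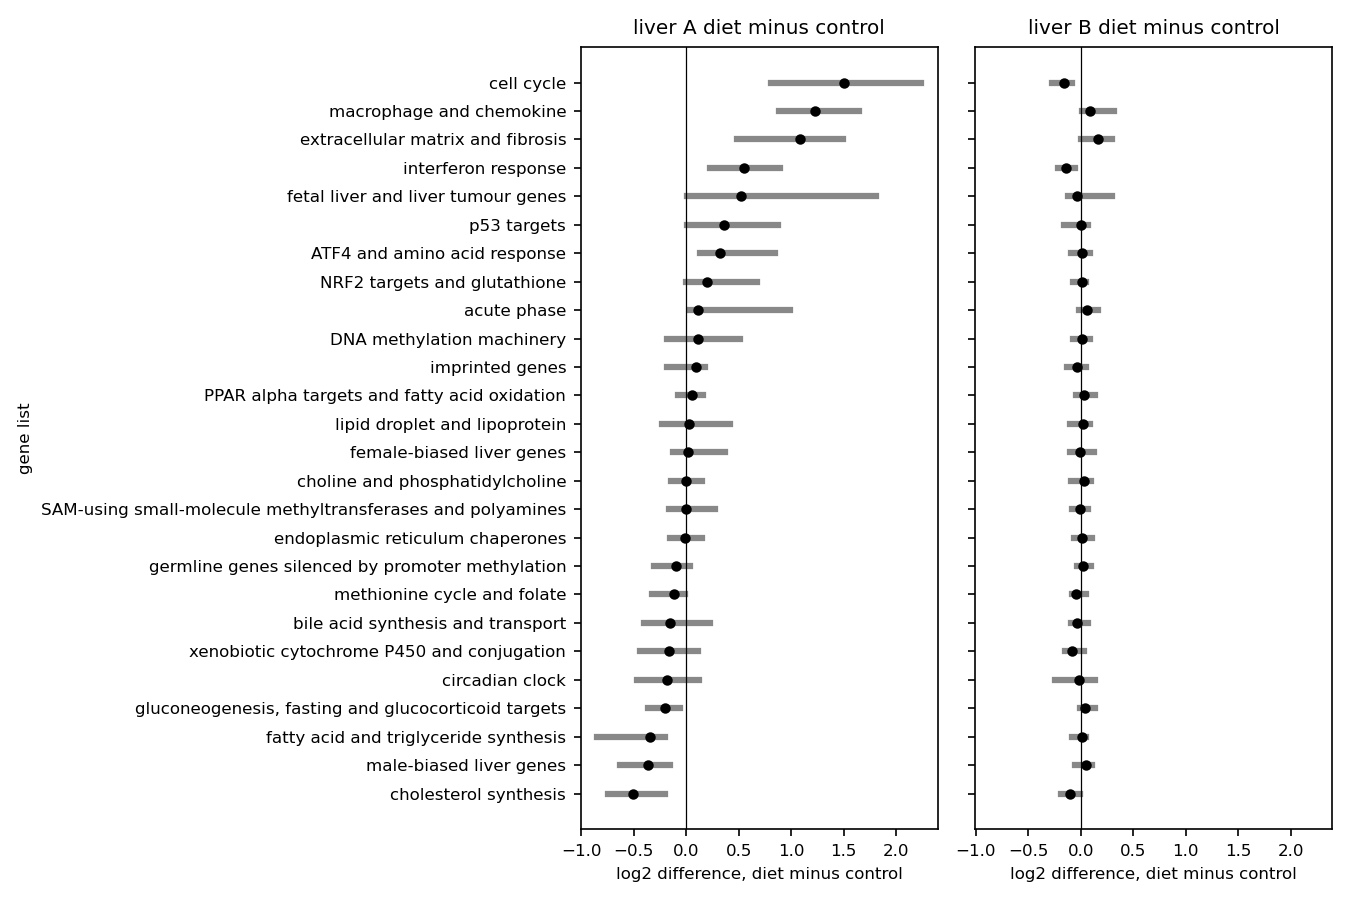
Median log2 difference (point) and the range from the lower to the upper quartile of members (bar) for 26 gene lists in liver, for group A on the left and group B on the right. The macrophage and chemokine list lies at 1.23 in group A and at 0.09 in group B.

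The next comparison asked how diet livers differed from their controls after 2 weeks of normal diet. A small set of genes differed. Mmp12 rose by 1.54 ± 0.21 (SE, n = 5 and 5), at least 1.31-fold since its controls lay under the background, and the chemokine Ccl5, which attracts T cells, by 1.25 ± 0.19. Cib3, a calcium-binding protein, rose by 1.46 ± 0.24, and Slc35f2, a carrier of the solute family, by 1.31 ± 0.21. Serpine2, an inhibitor of serine proteases, fell by 1.00 ± 0.12, Satb1, a chromatin organiser, by 0.73 ± 0.09 and Igsf10 by 0.93 ± 0.12. The controls of Ccl5 (mean 7.60) and Slc35f2 (7.33) and the diet livers of Igsf10 (7.62) also averaged under the background.

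The other genes among the 12 largest rises were Ehbp1, Timmdc1, Pam, Sppl2a, Ago1, Cbx3-ps5, Rgs5 and Ifi27l2b, between 0.83 and 1.28. Among the 12 largest falls were Ddit4, a stress-induced inhibitor of growth signalling (-0.98), Palm, the endothelial nitric oxide synthase Nos3 (-0.72), Krt80, Col13a1, H4c9, Mfsd3, She and the xenobiotic receptor Nr1i2 (-0.48). Among the genes of methyl group metabolism neither Gnmt (0.00 ± 0.08) nor Dnmt1 (-0.22 ± 0.09) passed the threshold.

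In the lists, 2 of 42 macrophage and chemokine genes rose, Ccl5 and Itgax (7 adjusted over the list alone, median 0.09, camera adjusted p = 1.1e-06), but adjusted p = 0.290 with an estimated correlation. Of the 36 matrix and fibrosis genes 1 rose, Mmp12 (3 rose and 1 fell adjusted over the list alone, median 0.17, camera adjusted p = 1.9e-06), but adjusted p = 0.290 with an estimated correlation. Of the 27 acute phase genes 1 rose, Saa3 at 0.55 (4 adjusted over the list alone, camera adjusted p = 0.006), but adjusted p = 0.290 with an estimated correlation. Among the T cell markers none passed alone (4 rose adjusted over the list alone, median 0.29, camera adjusted p = 8.6e-04), and adjusted p = 0.290 with an estimated correlation. By the median of the members 5 of 5 diet livers were higher. By the mean score 4 of 5 were (0.20 to 0.39), and diet animal 1 at -0.05 lay under every control of its group. Only 3 of those 9 markers had a mean above background. Stellate cell markers had 1 of 10 higher, Rgs5 at 0.89 (2 adjusted over the list alone, camera adjusted p = 0.022), but adjusted p = 0.505 with an estimated correlation. The cell cycle list (median -0.16, camera adjusted p = 8.6e-04) and the interferon list (median -0.14, camera adjusted p = 0.002) tested down with no member past the threshold in either, and adjusted p = 0.759 for both with an estimated correlation. The other 33 lists did not pass, with camera adjusted p from 0.053 to 0.979, and 31 of them had no member past the threshold. In 9 of those 33 the median, the mean and the test differed in sign, which none of the called lists showed.

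In all, 120 probe sets differed in group B livers, 93 higher and 27 lower, of 42575. Within the 3 slides that held both groups limma gave 9, 0 and 0 probe sets, with 3964, 2829 and 2454 at an unadjusted p under 0.05. By chance alone a share of 0.05 of all 42575 lies under that p. A fit on single arrays kept 114 of the 120 calls without and 106 with the slide as a block. The count ranged from 17 without diet animal 3 to 227 without diet animal 1. The 2 arrays of control 3 (r = 0.08) and of diet 2 (r = -0.10) correlated under 0.1 in their deviations, so a mislabelled array is possible there. Without these samples the count was 21, in a smaller set of animals, and 19 of the 120 calls were kept. The deposited column of control 3 equals its first array alone, while both of its arrays were averaged here. With the deposited table, which also differs in normalization, 57 of the 120 calls were kept. Of the 26 named genes that passed, 8 kept their call with each animal left out in turn, Mmp12, Cib3, Slc35f2, Ccl5, Cbx3-ps5, Serpine2, Igsf10 and Satb1. Without control 3 and diet 2 together Ccl5 (adjusted p = 0.056) and Cib3 (0.070) no longer passed.

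Whether the effect of the diet on the liver differed between groups A and B was tested directly. Among the largest differences of effects were those of a lipid droplet gene, of genes of cell division and of lipase-family genes. The difference of effects was 4.03 ± 0.36 for D17H6S56E-5, 3.62 ± 0.31 for Ccn5, a matrix-associated signalling protein, 3.47 ± 0.35 for Cidec, 3.39 ± 0.21 for Gsta1, 3.38 ± 0.27 for Ccnb1 and 3.37 ± 0.31 for Cdc20, which drives exit from mitosis. In the other direction it was -3.49 ± 0.29 for Pnpla5, -3.32 ± 0.30 for Pnpla3, -2.75 ± 0.27 for Sorcs2, -2.61 ± 0.23 for Slc2a4, -2.42 ± 0.19 for Lrit2 and -2.39 ± 0.37 for Ces4a. The Sorcs2 controls of group A averaged 10.25 on the log2 scale, while those of group B lay between 6.68 and 7.65, under the background, where a fall cannot be measured. Gsta1 averaged 9.43 in group A controls, 13.11 in group A diet, 12.37 in group B controls and 12.66 in group B diet livers. Its group B controls thus lay near the group A diet level, unlike those of the other genes with a higher effect in group A. Slc2a4 averaged 11.04, 8.14, 9.35 and 9.06 in that order. The group B controls of Pnpla5, Pnpla3 and Ces4a also lay below those of group A, and those of Lrit2 above. In all 6771 probe sets differed, 4026 with a higher and 2745 with a lower effect in group A. Of the 12195 probe sets called in group A, 6151 were also called in this test in the same direction, and 44 were called in group B in the same direction. Of the 120 called in group B, 65 were not called in group A and 11 were called there in the opposite direction, among them Ddit4 (0.68 in group A and -0.98 in group B). Both groups had 34 probe sets higher, 10 lower and 11 opposite, where independent calls would give 13.3, 3.87 and 17.2.

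The third comparison asked what 8 weeks on the deficient diet did to the kidney. Genes for a cytochrome P450, a carbonic anhydrase and a hormone receptor were among the largest rises, and segments of antibody genes made up most of the largest falls. Cyp2d12, a cytochrome P450, rose by 1.46 ± 0.14 (SE, n = 5 and 6), or 2.75-fold, and Car9, a carbonic anhydrase induced by low oxygen, by 1.32 ± 0.11. Igfbp1, which binds insulin-like growth factors, rose by 1.24 ± 0.23 and Prlr, the prolactin receptor, by 1.23 ± 0.20. Gbp8, an interferon-induced GTPase, fell by 1.44 ± 0.16, or 2.71-fold, and Cxcl1, a chemokine for neutrophils, by 1.12 ± 0.19.

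The other large rises were Ces1g (1.48), Depp1, a target of FOXO transcription factors (1.40), Stab2, a scavenger receptor (1.25), Clec2h (1.24), Ang (1.19), Dpys, an enzyme of pyrimidine breakdown (1.19), Rnase4 (1.08) and Bex4 (1.05). Hepatocyte transcripts differed in amount between the kidney samples, with Alb between 10.04 and 14.83 on the log2 scale, and Ces1g and Stab2 were highest in the same sample as Alb, kidney A diet 5. With the scores of 4 other tissues as covariates, Stab2 stayed at 1.21 and Dpys at 1.27, and Ces1g passed with adjusted p = 0.001. Bhmt, a betaine methyltransferase of liver and kidney cortex, was 1.20 ± 0.43 higher without passing, and Mat1a was at 0.47 ± 0.88. Both were also highest in kidney A diet 5. Of the 12 largest falls, 8 were variable or constant segments of antibody genes, such as Igkv4-53 (-1.43), Ighg1 (-1.07) and Ighv1-75 (-1.02). The others were Gbp8, Cxcl1, the matricellular gene Ccn1 (-1.08) and Cox6a2, a subunit of cytochrome oxidase (-1.11).

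In the cell cycle list 9 of 35 genes fell (21 adjusted over the list alone, median -0.40, lower by the median of the members in 5 of 5 diet kidneys, camera adjusted p = 8.6e-19), including Cdk1 (-0.91), Ccnb2 (-0.80) and Top2a (-0.77). With an estimated correlation that list had adjusted p = 0.077. T cell markers had 1 of 9 lower, Cd4 at -0.72 (5 adjusted over the list alone, median -0.37, camera adjusted p = 2.1e-08), and adjusted p = 0.113 with an estimated correlation. B and plasma cell markers had 1 of 8 lower, Jchain at -0.90 (3 adjusted over the list alone, median -0.27, camera adjusted p = 4.7e-04), and adjusted p = 0.253 with an estimated correlation. In the macrophage and chemokine list 3 of 42 fell, Cxcl1, Gpnmb and Lyz1 (1 rose and 5 fell adjusted over the list alone, median -0.14, camera adjusted p = 3.4e-05), and adjusted p = 0.535 with an estimated correlation. The interferon list tested up with no member past the threshold (2 adjusted over the list alone, median 0.12, camera adjusted p = 0.012), and adjusted p = 0.584 with an estimated correlation. Red blood cell markers tested down with no member past the threshold (none adjusted over the list alone, median -0.16, camera adjusted p = 0.034), and adjusted p = 0.253 with an estimated correlation. The exocrine pancreas list also tested down (median -0.90, camera adjusted p = 1.7e-04), and adjusted p = 0.584 with an estimated correlation. It had 1 of 11 members above background, and 1 control kidney carried its transcripts, with a score of 4.58.

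Transporters of the renal tubule had 3 of 40 genes higher (3 adjusted over the list alone, camera adjusted p = 0.059), the amino acid transporters Slc7a9 (0.51) and Slc7a7 (0.40) and the phosphate transporter Slc34a3 (0.69). Among intercalated cell markers the chloride exchanger Slc26a4 rose by 0.69 (1 of 8, 1 adjusted over the list alone). Of 23 kidney injury genes Krt18 rose by 0.73 and Ccn1 fell (3 and 3 adjusted over the list alone, camera adjusted p = 0.764). Of 39 ATF4 targets Igfbp1 and Sesn2 (0.61) rose and Slc38a2 (-0.52) fell (2 and 3 adjusted over the list alone, camera adjusted p = 0.978). Of 40 methionine cycle and folate genes 1 rose, Ftcd at 0.89 (1 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.897). Single members also passed in the P450 list (Cyp2a5, 0.74), the NRF2 list (Gsta3, 0.50), the p53 list (Gtse1, -0.57) and, through Igfbp1, the gluconeogenesis list. In all, 33 of 40 lists did not pass, with camera adjusted p from 0.059 to 0.979, and 24 of them had no member past the threshold. These 24 included the proximal tubule, thick ascending limb, distal tubule, principal cell, podocyte and endothelial markers, with medians of 0.03, 0.07, 0.09, 0.07, 0.09 and 0.05.

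In all, 441 probe sets differed in group A kidneys, 248 higher and 193 lower. The 4 controls and 3 diet animals on 1 slide gave 6 probe sets, and the 6 and 5 on another gave 139. The second arrays of controls 3 and 5 and of diet animals 3 and 5 lay on 2 further slides with group B livers. The authors' normalization within slides thus took kidney and liver arrays together there. In the deposited table these samples had medians from 8.735 to 8.8, and the other group A kidneys from 9.005 to 9.04. A fit on single arrays kept 423 of the 441 calls both without and with the slide as a block, 419 of them in both. The 2 arrays of diet animal 3 correlated at 0.07, and without it 405 probe sets differed. The deposited table gave 241 probe sets, and leaving out the 4 kidneys with adrenal or pancreas transcripts gave 193 in a smaller set of animals. In that smaller set Depp1 (adjusted p = 0.085), Igfbp1 (0.055), Igkv4-53 (0.092), Ccn1 (0.081) and Ighg1 (0.060) no longer passed.

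**Figure D3:**
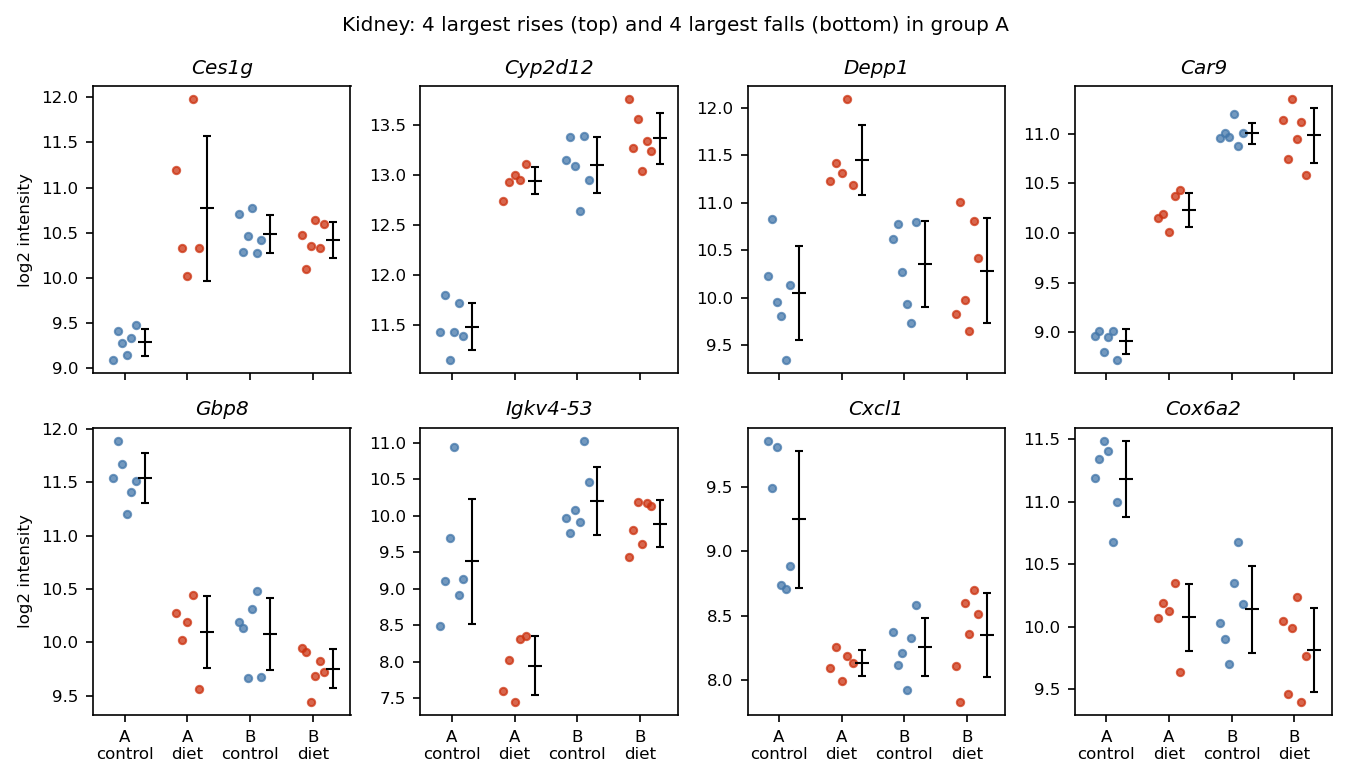
Log2 intensity per kidney sample for the 4 largest rises (top) and the 4 largest falls (bottom) of group A, with controls in blue, diet animals in red, and the mean with its SD beside each group. For Car9 the group A diet kidneys averaged 10.23 and their controls 8.91.

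**Figure D4:**
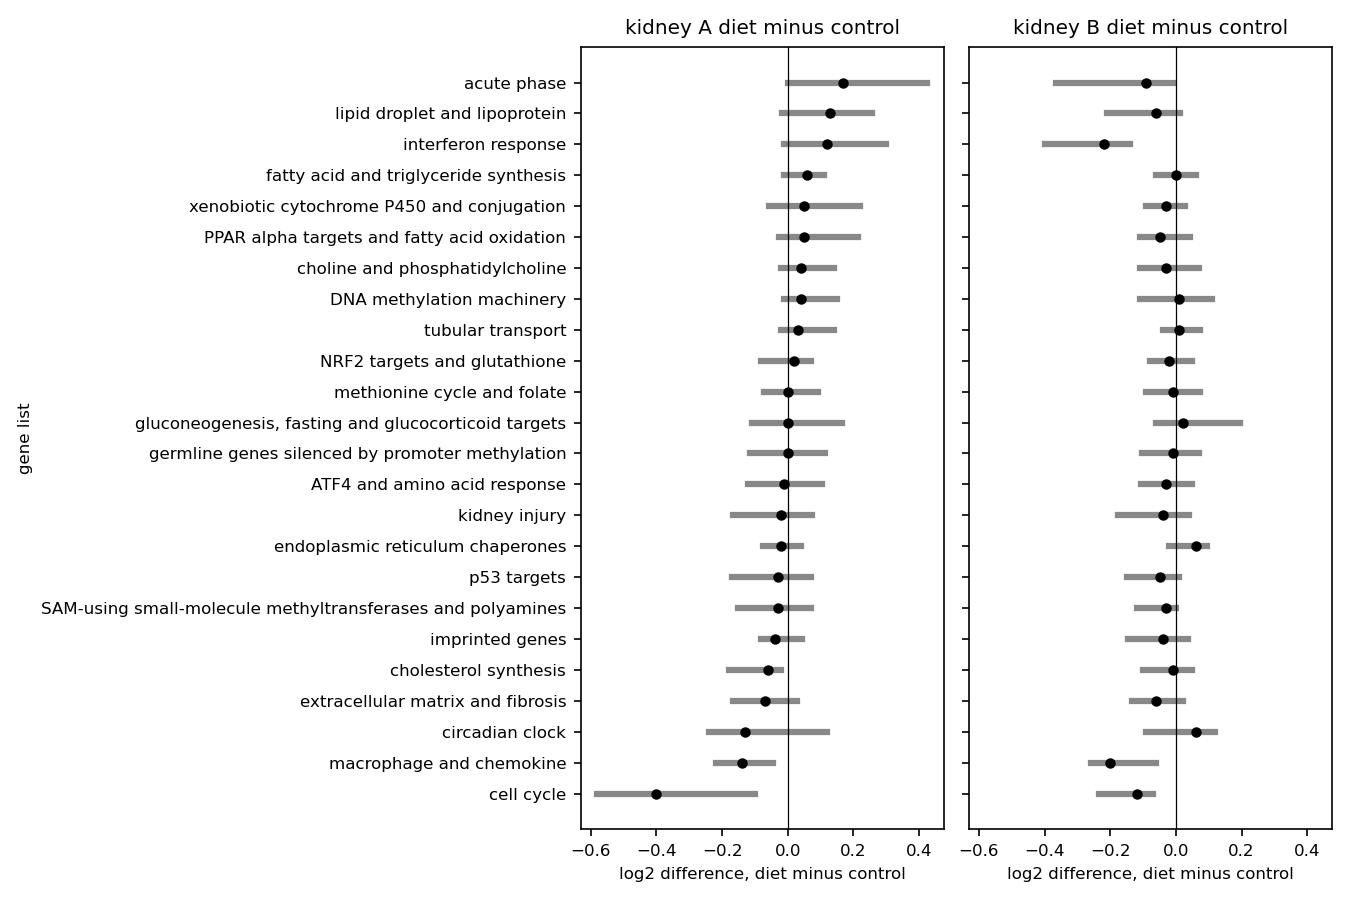
Median log2 difference (point) and the range from the lower to the upper quartile of members (bar) for 24 gene lists in kidney, for group A on the left and group B on the right. The cell cycle list lies at -0.40 in group A and at -0.12 in group B.

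**Figure D5:**
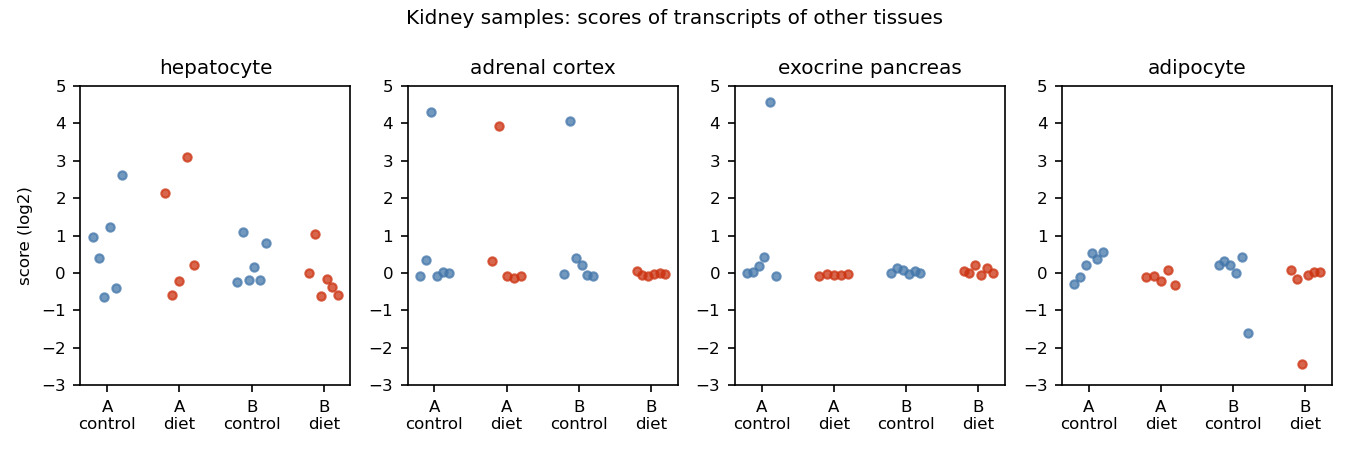
Score of each kidney sample on 4 marker lists of other tissues, as log2 relative to the median sample, with controls in blue and diet animals in red. Adrenal transcripts stand out in 3 kidneys (4.31, 4.06 and 3.93) and pancreas transcripts in 1 (4.58).

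The kidney after 2 weeks of normal diet showed few differences. Cbl, a ubiquitin ligase that turns off growth factor receptors, rose by 0.67 ± 0.08 (SE, n = 6 and 6), or 1.59-fold. N4bp2l2 (0.58 ± 0.10), the water channel Aqp4 (0.57 ± 0.11), the nuclear receptor Nr2c2 (0.50 ± 0.08) and Phip (0.40 ± 0.07) passed too, and no named gene fell. With the replicate number as a block Cbl kept its call (adjusted p = 0.004), while N4bp2l2 (0.057), Aqp4 (0.079), Nr2c2 (0.063) and Phip (0.080) did not. Among the genes of methyl group metabolism neither Chdh (0.21 ± 0.11) nor Mtr (0.22 ± 0.10) passed. Interferon response genes tested down (median -0.22, lower by the median of the members in 6 of 6 diet kidneys, 8 of 33 adjusted over the list alone and none over all probe sets, camera adjusted p = 4.4e-10), and adjusted p = 0.881 with an estimated correlation. The macrophage list (median -0.20, 1 adjusted over the list alone, camera adjusted p = 2.1e-07) and the cell cycle list (median -0.12, none adjusted over the list alone, camera adjusted p = 3.8e-04) tested down with no member past the threshold over all probe sets, and adjusted p = 0.881 for both with an estimated correlation. The other 37 lists did not pass, with camera adjusted p from 0.411 to 0.966, and Aqp4 was the single member of any of them past the threshold. In 6 of these lists the median, the mean and the test differed in sign.

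In all, 23 probe sets differed in group B kidneys, 21 higher and 2 lower, and 4 with the replicate number as a block, since samples of the same number deviated together there. These also lay side by side on both slides, so the animals and the place on the slide cannot be told apart as the source. Over both kidney groups the median correlation of diet and control arrays of the same number was 0.21 on 1 slide and 0.08 across slides. On 1 slide the arrays of control 4 and diet 4 correlated at 0.60 in their deviations. With their own second arrays they reached only 0.18 and 0.29, so a mislabelled or mixed array is possible there too. The other array of the same sample was the best match for 29 of 46 kidney arrays and 29 of 44 liver arrays. The 2 slides taken alone gave 0 each by limma, with 2456 and 3845 probe sets at an unadjusted p under 0.05. By chance alone a share of 0.05 of the 42575 probe sets lies under that p. Leaving out 1 animal gave between 6 (without control 2 or 3) and 206 (without diet animal 4). The deposited table gave 3, and 1 of the 23 calls was kept there. Of the 5 named genes Cbl alone kept its call with each animal left out in turn.

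The kidney effect of group A minus that of group B was 1.34 ± 0.15 for Car9, 1.19 ± 0.19 for Cyp2d12, 1.55 ± 0.31 for Ces1g, 1.41 ± 0.30 for Dpys, 1.34 ± 0.26 for Stab2 and 1.21 ± 0.21 for Insc. It was -1.19 ± 0.23 for Tbc1d16, -1.12 ± 0.22 for Gbp8, -0.98 ± 0.19 for Ighv1-43, -0.95 ± 0.14 for Tstd2, -0.89 ± 0.16 for Slc4a7 and -0.84 ± 0.12 for Cbl. Of these 12 genes 7 kept their call with each animal left out in turn, and Ces1g, Dpys, Stab2, Gbp8 and Tbc1d16 did not. The 2 sets of controls differed in level, in a test added after the results had been seen. Car9 averaged 8.91 in group A controls, 10.23 in group A diet, 11.00 in group B controls and 10.99 in group B diet kidneys. Cyp2d12 averaged 11.48, 12.94, 13.10 and 13.37 in that order, Gbp8 11.54, 10.10, 10.07 and 9.75, and Cbl 11.38, 11.20, 10.56 and 11.23. Of all probe sets 15228 differed between the control kidneys of groups A and B, which lay on separate slides. Of the 441 probe sets called in group A, 221 had group A controls apart from group B controls on the same side as from group A diet kidneys. In liver 4280 differed between the sets of controls, which also lay on separate slides, and 1028 of the 12195 did so on that side. Slide, time and group cannot be told apart in that difference, and a smaller effect in group B is therefore not shown to be a return to the control level of group A. In all 92 probe sets differed in effect, 54 up and 38 down, and 45 without diet animal 1 of group A. With the replicate number as a block 74 differed and 45 of the 92 calls were kept. Of the 12 genes Car9, Cyp2d12, Stab2, Insc, Gbp8, Tstd2 and Cbl passed with that block, while Ces1g (adjusted p = 0.068), Dpys (0.055), Tbc1d16 (0.064), Ighv1-43 (0.085) and Slc4a7 (0.060) did not. Of the 441 probe sets called in group A, 68 were also called in this test in the same direction and none was called in group B in either direction.

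The effects on liver and kidney were set against each other with both tissues normalized together. In group A the liver effect exceeded that of the kidney by 4.45 ± 0.34 in D17H6S56E-5, 4.35 ± 0.25 in Mmp12, 4.29 ± 0.36 in Gpnmb, a macrophage glycoprotein, 3.97 ± 0.24 in the spindle protein gene Ckap2, 3.96 ± 0.28 in Ccn5 and 3.95 ± 0.26 in Ccnb1-ps. It lay below it by -3.43 ± 0.24 in Pnpla5, -3.11 ± 0.30 in Obp2a, -2.93 ± 0.37 in Sorcs2, -2.88 ± 0.55 in Pnpla3, -2.88 ± 0.21 in Slc2a4 and -2.78 ± 0.22 in Lrit2. In all 7207 probe sets differed between the tissues, 3921 with a higher and 3286 with a lower effect in liver. Of the 12195 probe sets called in group A livers, 51.7% had the same sign in group A kidneys, against at most 54.6% over 99 exchanged labellings of the kidneys. Both tissues had 68 probe sets higher and 32 lower, where independent calls would give 35.5 and 27.7, and 114 moved in opposite directions, where independent calls would give 63.2.

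In group B the liver effect exceeded that of the kidney by 2.00 ± 0.26 in Mmp12, 1.44 ± 0.22 in Slc35f2, 0.95 ± 0.19 in H2-DMb2, which loads antigen peptides, 0.86 ± 0.16 in Alpk1, 0.82 ± 0.14 in Mtmr11 and 0.79 ± 0.16 in Myo1f. It lay below by -0.97 ± 0.17 in Igsf10, -0.90 ± 0.19 in the chromatin remodelling gene Arid2, -0.85 ± 0.15 in Serpine2, -0.81 ± 0.16 in the histone chaperone gene Hira and -0.81 ± 0.14 in Dgkh. Of these genes Arid2, H2-DMb2, Hira and Myo1f lost their call with some animal left out. In all 26 probe sets differed, 18 up and 8 down, and 9 without diet animal 3 of the liver. With each array scaled to a common median there were 14, of which 57.1% had a higher effect in liver, against 69.2% of the 26.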

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

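Of the tests in this part, those of the slides and the normalization in liver A and of the tissue scores as covariates in kidney A were chosen after the result had been seen, as were the use of the slide block with its reference fit in all 3 comparisons argued below and the overlap of calls in liver B.

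Single samples far from the rest of their group were looked for as a gap to the nearest sample, divided by the group's range. Among the named genes 10 of 234 groups had such a sample, where chance gives about 1 in 20, or 11.7. Among them were Gpnmb in liver A control 3 (0.799), Slc2a4 in liver A diet 2 (0.717), Lrit2 in liver A control 3 (0.709), Cib3 in liver B diet 1 (0.842), Mfsd3 in liver B diet 4 (0.783), Depp1 in kidney A diet 5 (0.743), Ighv1-19 in kidney A diet 2 (0.739), Mat1a in kidney B diet 2 (0.845) and Cbs in kidney B diet 3 (0.625).

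Among the scores of marker lists 15 of 128 groups had such a sample, where chance gives 6.40. In kidney they were the adrenal cortex score in A control 3 (0.902), A diet 2 (0.889) and B control 2 (0.886), the exocrine pancreas score (0.893) and the gallbladder and bowel score (0.886) in A control 5, the adipocyte score in B control 6 (0.799) and B diet 3 (0.898), the intercalated cell score in B diet 3 (0.636), the hepatocyte score in B diet 2 (0.628) and the muscle score in B diet 5 (0.700). In liver they were the exocrine pancreas score in B diet 1 (0.800), the gallbladder and bowel score in A control 5 (0.770), the proximal tubule score in A control 4 (0.819), the red blood cell score in A diet 5 (0.647) and the muscle score in A control 3 (0.679). In kidney A control 3 the adrenal enzyme Cyp11b1 reached 12.82 against a median kidney of 6.04, and in kidney A control 5 the pancreatic lipase Pnlip reached 10.98 against 5.95.

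Diet effects that differed between groups A and B or between tissues were found by a direct test of the difference. In liver 6771 probe sets differed between A and B, with D17H6S56E-5 (4.03), Ccn5 (3.62), Cidec (3.47), Gsta1 (3.39), Ccnb1 (3.38) and Cdc20 (3.37) higher and Pnpla5 (-3.49), Pnpla3 (-3.32), Sorcs2 (-2.75), Slc2a4 (-2.61), Lrit2 (-2.42) and Ces4a (-2.39) lower. In kidney 92 differed, with Ces1g (1.55), Dpys (1.41), Stab2 (1.34), Car9 (1.34), Insc (1.21) and Cyp2d12 (1.19) higher and Tbc1d16 (-1.19), Gbp8 (-1.12), Ighv1-43 (-0.98), Tstd2 (-0.95), Slc4a7 (-0.89) and Cbl (-0.84) lower. Between liver and kidney 7207 differed in group A, with D17H6S56E-5 (4.45), Mmp12 (4.35), Gpnmb (4.29), Ckap2 (3.97), Ccn5 (3.96) and Ccnb1-ps (3.95) higher and Pnpla5 (-3.43), Obp2a (-3.11), Sorcs2 (-2.93), Pnpla3 (-2.88), Slc2a4 (-2.88) and Lrit2 (-2.78) lower. In group B 26 differed, with Mmp12 (2.00), Slc35f2 (1.44), H2-DMb2 (0.95), Alpk1 (0.86), Mtmr11 (0.82) and Myo1f (0.79) higher and Igsf10 (-0.97), Arid2 (-0.90), Serpine2 (-0.85), Hira (-0.81) and Dgkh (-0.81) lower.

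Other splits of the same samples were drawn 100 times per comparison, the real split included. The real split alone gave as many probe sets (1 of 100) in liver A (12195, highest other 5154), liver A against B (6771, highest other 6113), kidney A (441, highest other 126), kidney A against B (92, highest other 27) and liver against kidney in A (7207, highest other 2170). As many came from 4 of 100 splits in liver B (120, highest other 307), 4 in kidney B (23, highest other 274) and 3 for liver against kidney in B (26, highest other 160). All these shares are under 0.05, without adjustment over the comparisons. In liver A and kidney A, where the real split alone reached its count, chance alone is an unlikely source. In liver B, kidney B and liver against kidney in B the shares lie near that bound and rest on a draw of splits. Chance is therefore not excluded there. The 100 splits also took no account of the numbered pairs of kidney B, which bears on kidney A against B as well. Splits with several times the real count point to a structure among the samples. In kidney B the split with 274 exchanged control 6 with diet 4. Among the 32 splits that part all numbered pairs there, the highest other gave 1 against 23, and with the replicate block the real split gave 4 and the highest other 1.

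The wide change in group A livers was weighed against slides, hepatocyte share and normalization. Over the probe sets called on the second arrays, the difference on the slide with both groups followed them with a slope of 0.79 (spread 0.05), where a slide effect as the whole cause needs a slope near 0. A fit on single arrays kept 11651 of the 12195 calls, and 7938 with the slide as a further block, where 180 had the opposite sign. Over all 12195 the differences with the block followed those without it at a slope of 0.96, which large differences dominate, and the median SE was 1.22 times as large. The sizes of the 3871 calls lost only with that block were not compared on their own. For these calls a part of the slides stays open. Since 1 slide held diet animals only, the diet effect with the block rested on the other slides, where both groups lay. A lower share of hepatocyte RNA as the only change raises other resident cell types alike, but their medians lay 0.64 apart (SE 0.26). That gap was the highest minus the lowest of 4 lists, and its SE takes no account of picking the extremes. Unequal medians cannot separate a change per cell from a changed mix of several cell types, which stays open. Median scaling and cyclic loess gave at least 12392 probe sets and moved the share of higher ones by at most 6.06 points. For the calls kept the diet remains a hypothesis consistent with these tests, which used the same data.

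For group A kidneys, dissection with more cortex or medulla was argued against by a difference of -0.01 (SE 0.06) between proximal tubule and the later tubule lists. Slides were argued against by a fit on single arrays, where adding the slide as a block lost 4 of the 423 calls kept without it. That fit took the 2 arrays of a sample as correlated by 0.15, and by 0.19 with the block, so arrays counted almost as animals. The slope of 0.99 (spread 0.05) between 2 slides ran over the called probe sets of largely the same animals, so it adds little. RNA of neighbouring tissues cannot be told apart from an effect of the diet for part of the probe sets. With 4 tissue scores as covariates 64.9% of the calls stayed, just on the side of the bound (2 of 3 calls) that the test had named as going with this explanation. All 441 kept their sign, with a median size of 0.60 before and 0.59 after, and the 155 lost calls went from 0.48 to 0.45 while their median SE rose from 0.11 to 0.12. Reading a loss as evidence only where the differences shrank was settled after the 64.9% had been seen.

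For group B livers, slides were weighed by a fit on single arrays, where adding the slide as a block lost 10 of the 114 calls kept without it. That fit took the 2 arrays of a sample as correlated by 0.06, and by 0.15 with the block. Arrays thus counted almost as animals, and the fit argues only weakly against slides. Fits within single slides, with fewer samples, kept 4, 0 and 0 of the 120 calls. The slope of 0.96 (spread 0.07) of the difference within slides on the reported one ran over the called probe sets, so it adds little. A remainder of the change in group A stayed open, since 64.2% of the 120 probe sets had the same sign in group A, above the 60 percent named in advance but under the 74.2% of the highest other split. Calls shared with group A were 34 higher and 10 lower, where independent calls would give 13.3 and 3.87, and 11 were opposite where they would give 17.2. That overlap goes with a remainder for some of the calls, but it was not set against other splits, and 65 of the 120 were not called in group A. More T cell RNA may contribute, with a T cell list median of 0.29 (SE 0.11), with 5 of 5 diet livers higher by the median of the members and 4 of 5 by the mean score, although that list had adjusted p = 0.290 with an estimated correlation. No test separated a change in cell number from a change per cell, and an effect of the earlier diet remains open.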

How the results depend on the processing

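Of these alternatives, the fits within slides, on single arrays without a slide block, of 2 groups without new normalization, without poorly correlated array pairs, without kidneys that carry adrenal or pancreas transcripts and with tissue scores were chosen after seeing the data. No called named gene reversed its sign under any alternative run, and counts were compared by size only. Single probe sets did reverse. Of the 12195 liver A calls 180 had the opposite sign with the slide as a block, and 281 within the slide with several animals of both groups. Of 157 called named genes in liver A 129 passed in every setting, as did 12 of 12 for liver A against B and 12 of 12 for liver against kidney in A, 1 of 11 (Mmp12) for liver against kidney in B, and 0 of 26 in liver B, 0 of 43 in kidney A, 0 of 5 in kidney B and 0 of 12 for kidney A against B. Unless stated, the cause was not tested. No scaling moved the median of all probe sets by over 0.1.

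Probe sets past the threshold changed by over 1.5 times as follows. With at least 1.5-fold, a stricter rule by construction, there were 4090 in liver A, 4191 for liver A against B, 225 in kidney A, 14 in kidney B and 4620 for liver against kidney in A. Without background correction there were 44 in liver B, 14 in kidney B and 17 for the tissues in B. With normexp offset 0 there were 30 in liver B, 14 in kidney B and 52 for kidney A against B. Median scaling gave 14 for the tissues in B, and the mean of probes 43 in kidney B. The deposited table gave 241 in kidney A, 3 in kidney B, 21 for kidney A against B and 40 for the tissues in B, and in liver B 89.8% of its calls were higher against 77.5%. With dim probe sets removed, which leaves fewer tests, there were 183 in liver B, 85 in kidney B and 162 for kidney A against B. The first array alone gave 7436 in liver A, 4 in liver B, 2977 for liver A against B, 120 in kidney A, 0 in kidney B, 7 for kidney A against B, and 3628 and 4 for the tissues in A and B. The second array alone gave 21 in liver B, 201 in kidney A, 3 in kidney B, 41 for kidney A against B and 1 for the tissues in B. Single arrays with the sample as a random block gave 366 in liver B, 1034 in kidney A, 392 in kidney B, 409 for kidney A against B and 97 for the tissues in B. The slide as a further block gave 219, 1058, 378, 404 and 88 in that order, so in kidney most of the move came with the single arrays. The compared groups alone, normalized anew, gave 9 in liver B and 1 in kidney B, and without new normalization 36 and 1.

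With 1 array for most samples, and in liver and on 1 kidney slide fewer samples, single slides gave 6510 in liver A, 9, 0 and 0 in liver B, 6 and 139 in kidney A and 0 and 0 in kidney B by limma. Where the count was 0, 2829 and 2454 (liver B) and 2456 and 3845 (kidney B) had an unadjusted p under 0.05. A share of 0.05 of the 42575 probe sets lies under that p by chance alone. Without poorly correlated array pairs there were 21 in liver B. Without kidneys that carry adrenal or pancreas transcripts there were 193 in kidney A, 7 in kidney B, 39 for kidney A against B and 17 for the tissues in B. With 4 tissue scores there were 6 in kidney B and 50 for kidney A against B. Of the gene lists 0 passed in liver B, kidney A and kidney B with an estimated correlation (7, 7 and 3 as reported), and 13 in kidney A with all probe sets of the listed genes.

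With the replicate number as a block there were 45 in liver B and 4 in kidney B. The numbers paired samples in kidney B only. For the tissues, the shared male number as a random block gave 7362 in A and 27 in B.

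Leaving out 1 animal gave 10930 to 12288 in liver A, 17 to 227 in liver B, 6032 to 6811 for liver A against B, 297 to 475 in kidney A, 6 to 206 in kidney B, 45 to 114 for kidney A against B, and 6488 to 7330 and 9 to 60 for the tissues in A and B. Counts moved by over 1.5 times in liver B without control 1 (78), 2 (69), 3 (60), 4 (40) or 5 (33) or diet 1 (227), 2 (71), 3 (17) or 4 (49). In kidney B they did so without control 2 (6), 3 (6), 4 (61) or 6 (54) or diet 1 (56), 2 (11), 3 (12), 4 (206), 5 (7) or 6 (7). For kidney A against B they did so without A control 3 (58), A diet 1 (45), B control 2 (61) or B diet 6 (58). For the tissues in B they did so without liver control 3 (15) or 4 (12), liver diet 1 (42) or 3 (9), kidney control 3 (16) or 5 (12), or kidney diet 1 (11), 2 (12), 3 (16), 4 (60) or 6 (13). Signal limits the dim genes, since 55.6% of probe sets in liver and 59.3% in kidney had a mean above background.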

Other observations

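The list of male-biased kidney genes tested here was written before its values were seen. Lower androgen action in the kidney may be a hypothesis for part of the change in group A. Of 15 such genes 0 rose and 1 fell by limma, Cyp7b1 at -0.29 (4 fell adjusted over the list alone). The list tested down by camera (p = 0.001, and p = 0.005 with an estimated correlation, neither adjusted), but its median was -0.06 (SE 0.04). The bound named in advance against this hypothesis was a median above -0.1, which was met by less than 2 times the spread, so the hypothesis stays open.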
